A study of Bos taurus with 6 samples.

How the data were processed

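Polyadenylated RNA from primary hepatocytes of newborn calves was sequenced in 6 libraries, 3 from cells treated with palmitic acid and DMSO and 3 with palmitic acid and 3-IAA. Per the labels, the submitters' notes name cutadapt 1.9, HISAT2 2.2.1, RSEM and DESeq2, without saying what each did; the genome build, the annotation and the use of strand in counting were not given in the sources used here. The authors' count table holds expected counts (estimated reads per gene) for 36577 loci, of which 36073 have Ensembl cattle identifiers and 504 are assembled loci, and 20335 have a gene name. Between 17.2% and 19.0% of a library's values had a fractional part, with any part above 0 counted. The deposited table also holds TPM (transcript abundance scaled to a common total) per library, group means of both units, and a length in bases for each locus per the file headers, which was not used here. The authors' deposited comparison gives a base mean signal (mean normalized count), a log2 fold change with its standard error, a Wald score (statistic), a p-value and an adjusted p-value for each gene. It was read only for comparing its fold changes, marks and adjusted p-values with the results here. Total counts were 20765358, 16580723 and 20090420 in PA + DMSO replicates 1 to 3 and 22562450, 21354569 and 21159388 in PA + 3-IAA replicates 1 to 3. At this depth 3 counts equal 0.133 to 0.181 CPM, a limit for counting error only.

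The labels give the groups and replicate numbers, and do not say whether same-numbered libraries share an animal, a culture or a day, so no replicate block was used. Expected counts were rounded and tested with R 4.3.3 and edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood test, two-sided, Benjamini-Hochberg over all 15576 genes tested, adjusted p under 0.05). Fold changes are fitted values of PA + 3-IAA over PA + DMSO, the SE is the size of the log2 fold change divided by the square root of the F statistic, and CPM values use TMM library sizes. The tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, except where the text says otherwise. The 38 fixed lists of pathways and cell type markers held 940 entries, of which 879 were matched by gene name and 5 of these by a synonym. The 37 lists with at least 5 tested members were tested with camera (limma 3.58.1; log2 CPM with a prior count of 2, preset correlation 0.01), again with an estimated correlation, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. No list passed camera with an estimated correlation. The smallest adjusted p there was 0.693, a value that many lists share through the adjustment, so it does not rank them. Annotation terms with 10 to 300 tested genes were tested by one-sided Fisher's exact test against tested genes with a term of that kind.

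The rule for named genes took SIRT3, HSPA5, DDIT3, PLIN2, CPT1A, CYP1A1 and AHR in any case; the 8 largest fitted rises and the 8 largest fitted falls among called genes with a gene name, a mean CPM of at least 5 over the 6 libraries and no overlap between the groups; and of each list described, up to 3 tested members with the smallest unadjusted p. Some genes that the rule takes are not reported here.

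The alternatives were DESeq2 1.42.0, limma voom, median-of-ratios (RLE) scaling, scaling by library total, no filter beyond a total above 0, a strict filter (CPM of at least 1 in each of the 6 libraries), the replicate number as a block, leaving out each library in turn and, for lists, an estimated correlation. Member counts per list under these settings, and the estimated correlation without PA + DMSO replicate 3, were added after seeing the data.

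The tests were also run on simulated data, in 10 simulations of 200 changed genes each, with between 15370 and 15399 genes. The number of simulations was raised from 1 after DESeq2 called more unchanged genes in the first than a bound set for it, and that bound was then dropped. edgeR recovered 69% of genes changed 1.5-fold, 88.2% at 2-fold and 98.2% at 4-fold, and unchanged genes made up 8.45% of its calls (157 of 1858), above the share that the threshold of 0.05 aims at. That share was 14.4% for DESeq2 and 7.36% for voom. In the data 51.2% of genes were called and PA + DMSO replicate 3 stood apart from its group. The simulations had neither trait, so their rates need not hold for the real comparison. The count table came with 2 lines emptied, which were not analysed here.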

Results

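Gene expression was measured by RNA sequencing in primary hepatocytes from calves, cultured with 400 µmol/L palmitic acid (PA), a saturated fatty acid. In 3 libraries the PA was given with the solvent DMSO (PA + DMSO) and in 3 with 200 µmol/L indole-3-acetic acid (3-IAA), a product of tryptophan breakdown (PA + 3-IAA). Total counts per library ranged from 16580723 to 22562450. Of 36577 loci in the count table, 15576 passed the filter on low counts and were tested. The study's title names lipid accumulation, endoplasmic reticulum (ER) stress and the mitochondrial deacetylase SIRT3, so the comparison asked how 3-IAA changed transcripts in hepatocytes under PA. No PA-free controls were among these samples, so each change is relative to PA with solvent. The labels do not say whether replicates came from separate calves or separate cultures, and p-values then measure only the spread between these libraries.

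The groups separated along the first principal component of log2 CPM (the read count normalised to library size), which held 92.4% of the variance over 10965 genes. The PA + 3-IAA libraries lay between 32.1 and 32.8 on it, and PA + DMSO replicates 1 and 2 at -42.6 and -42.3. PA + DMSO replicate 3 stood apart from its group, at -12.7. For this reason, the counts of genes and of members of the lists that passed camera are also given without that library, for list members as an alternative chosen after seeing the data.

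**Figure D1:**
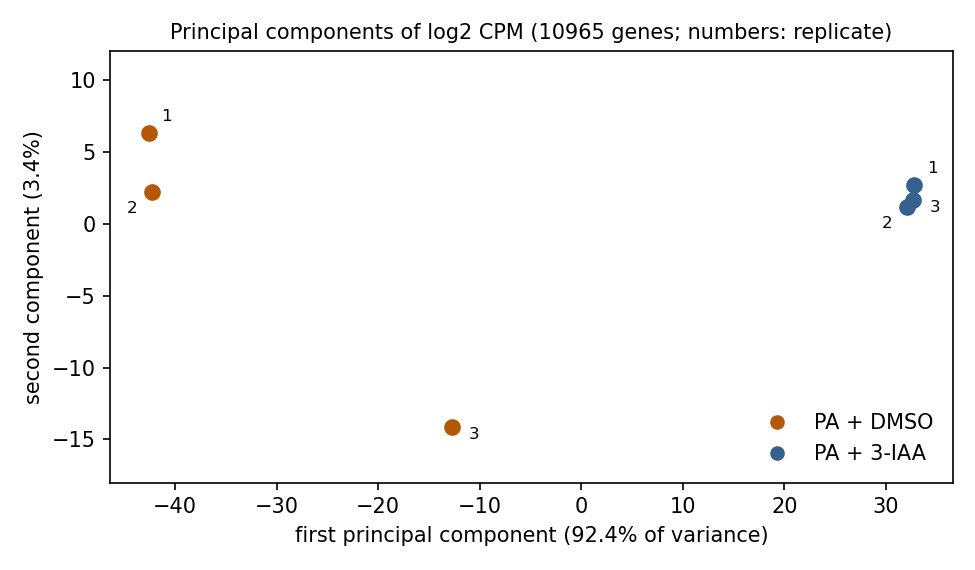
First (x) and second (y) principal components of log2 CPM over 10965 genes, one point per library, numbered by replicate. PA + DMSO replicate 3 lies at -12.7 on the first component, between its group's other libraries and the 3 PA + 3-IAA libraries.

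With 3-IAA, transcripts of ER chaperones, of the integrated stress response and of the lipid droplet protein PLIN2 were lower, while hepatocyte, acute phase and interferon-stimulated genes were higher. HSPA5, the main ER chaperone (BiP), went from 23180 ± 6113 CPM (SD, n = 3) to 1150 ± 22.2 CPM, a 20.2-fold fall. PLIN2, which coats lipid droplets, went from 1777 ± 244 to 328 ± 16.3 CPM, a 5.42-fold fall. SIRT3 rose 2.71-fold, from 2.07 ± 0.56 to 5.62 ± 1.02 CPM. In edgeR's quasi-likelihood test 3963 genes were higher and 4015 lower with 3-IAA at a Benjamini-Hochberg adjusted p under 0.05, which was 51.2% of the genes tested. Of these, 705 were higher and 842 lower by at least 2-fold. Without PA + DMSO replicate 3 the numbers were 4918 higher and 4726 lower, and at 2-fold 1205 higher and 1096 lower. The groups' CPM values did not overlap for 62.5% of genes, where chance alone gives 10%.

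**Figure D2:**
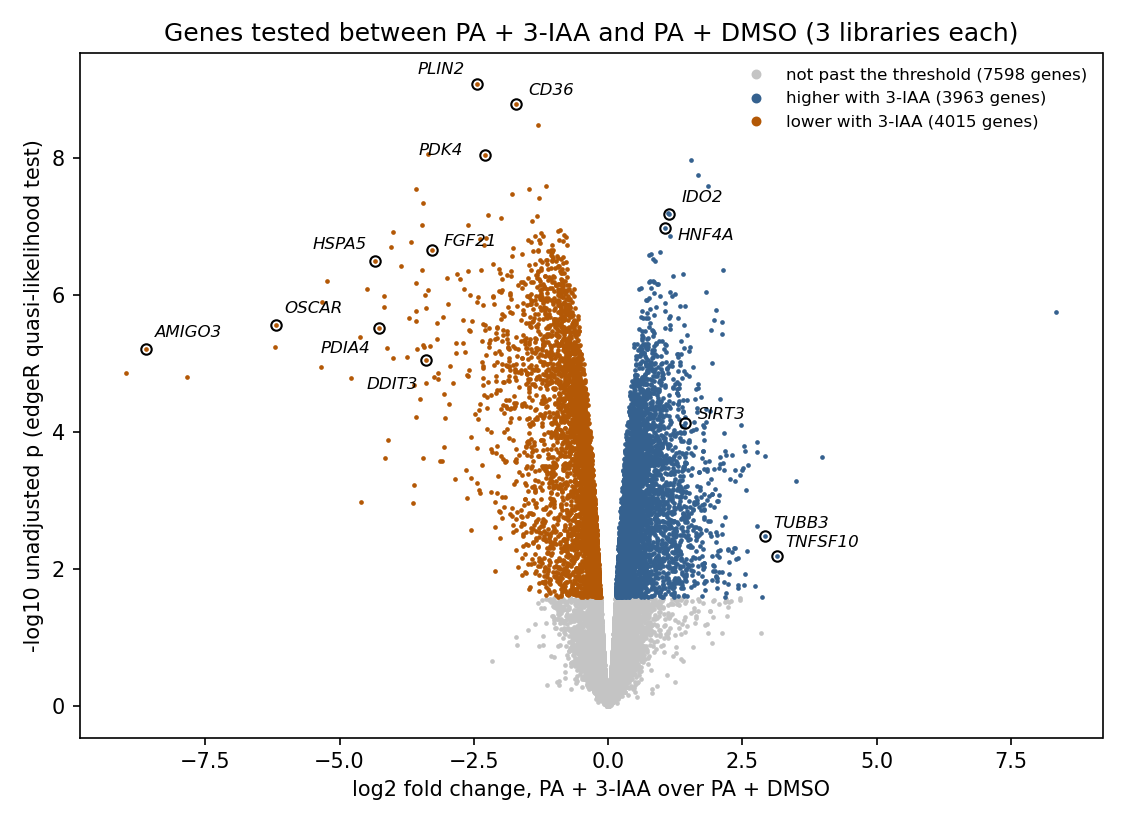
Log2 fold change of PA + 3-IAA over PA + DMSO (x) against -log10 of the unadjusted p of edgeR's quasi-likelihood test (y), one point per gene tested. The 3963 higher and 4015 lower genes are coloured, and PLIN2 and CD36 have the smallest p among the genes circled and named.

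Genes of ER protein folding and of ER-associated degradation fell almost throughout: 29 of 30 tested members were lower with 3-IAA and none was higher, with a median log2 fold change of -1.88. HSPA5 changed by -4.33 (log2, SE 0.22, adjusted p = 6.43e-05). SELENOK, a selenoprotein of the ER membrane, changed by -1.30 (SE 0.10, adjusted p = 6.41e-05) and XBP1, a transcription factor of the unfolded protein response, by -1.07 (SE 0.09, adjusted p = 6.89e-05). PDIA4, an ER disulfide isomerase, fell 19.3-fold and DERL3, an ER degradation factor, 24.7-fold. EDEM2, at -0.09, was the member that did not pass the test (named after its value was seen). In the competitive list test camera, with a preset correlation of 0.01 between genes, the list was lower with an adjusted p of 4.76e-15 (adjusted p = 0.693 with an estimated correlation, and 0.295 with that and without PA + DMSO replicate 3). The counts adjusted over the list alone and those without PA + DMSO replicate 3 were also 29 lower and 0 higher.

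Targets of the integrated stress response, the program run by the transcription factors ATF4 and CHOP, fell as well. Of 30 tested members 28 were lower and none higher, with a median of -0.83 and the same counts adjusted over the list alone. DDIT3, which encodes CHOP, went from 343 ± 94.9 to 32.8 ± 1.47 CPM, a 10.5-fold fall (log2 -3.39, SE 0.24, adjusted p = 0.000176). FGF21, a hormone that hepatocytes release under stress, fell 9.76-fold from 7.26 ± 1.5 CPM. PPP1R15A, a phosphatase subunit that reverses the block of translation, fell 3.56-fold and the transcription factor ATF3 fell 2.15-fold. The list's adjusted p was 6.99e-10 by camera (adjusted p = 0.693 with an estimated correlation, and 0.234 with that and without PA + DMSO replicate 3). Without that library 29 members were lower.

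**Figure D3:**
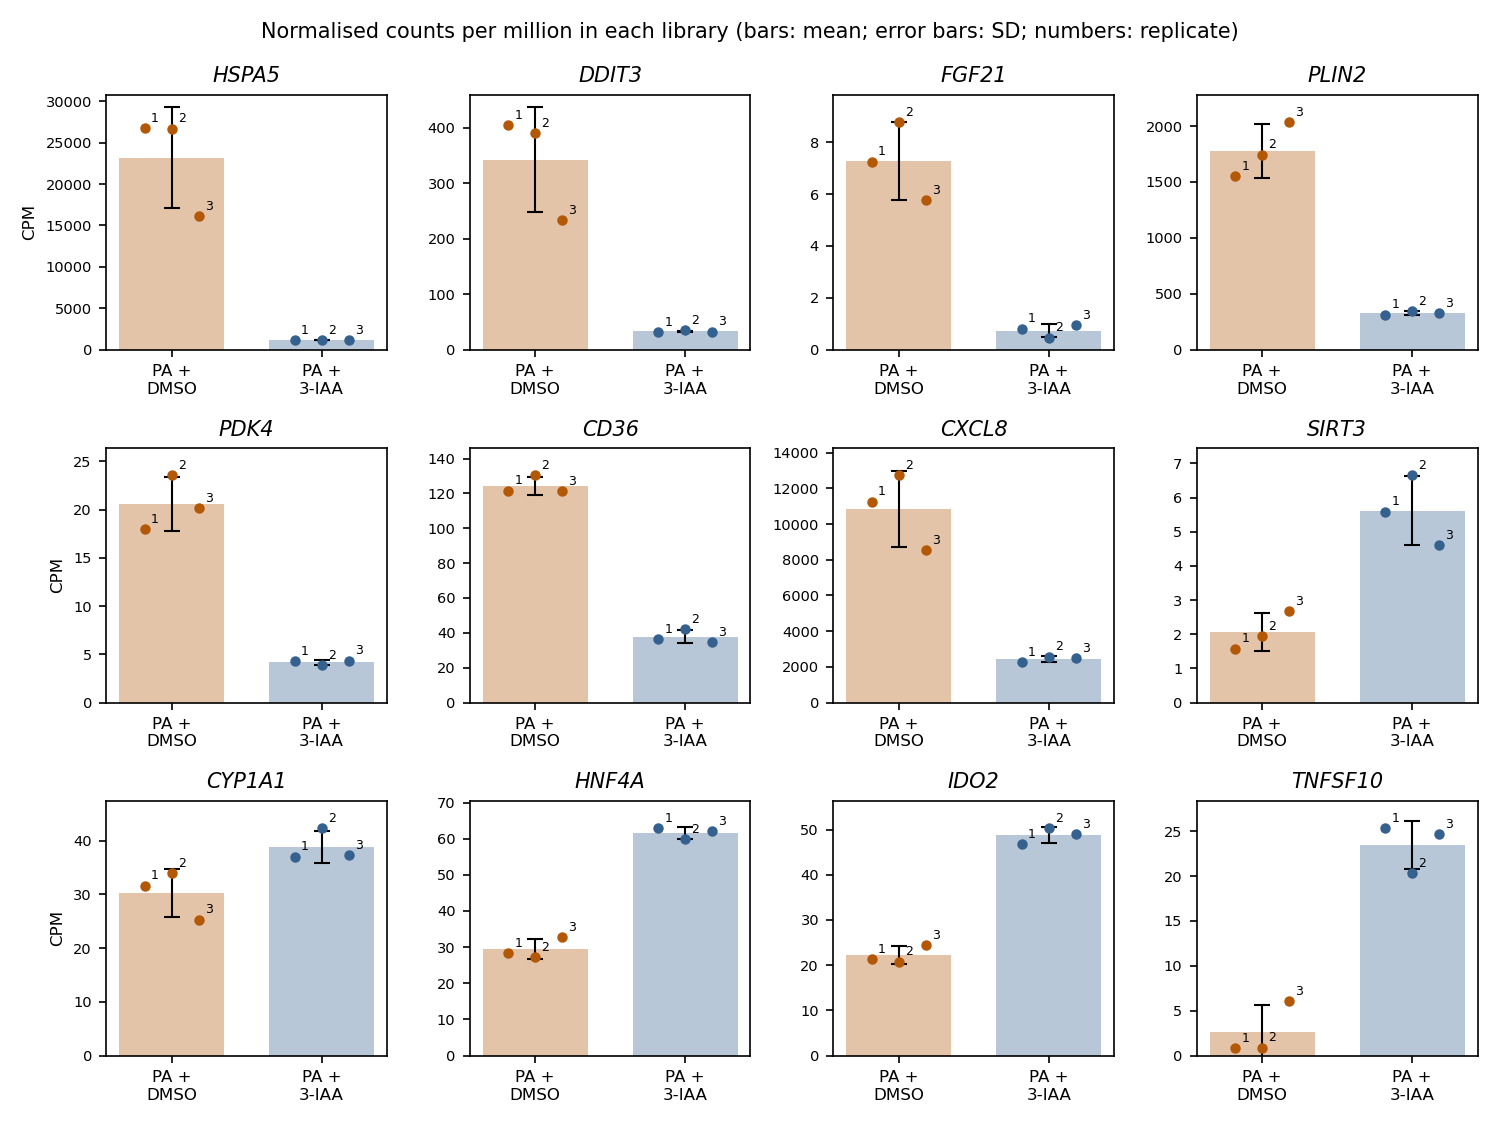
CPM (y, each panel on its own scale from 0) of 12 genes in PA + DMSO and PA + 3-IAA; points are libraries numbered by replicate, bars are means and error bars are SD over 3 libraries. PA + DMSO replicate 3 lies below replicates 1 and 2 for HSPA5 and DDIT3 and above them for PLIN2.

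Genes that handle fatty acids moved in both directions. PLIN2 had a log2 fold change of -2.44 (SE 0.10, adjusted p = 1.24e-05). CD36, a fatty acid transporter of the plasma membrane, went from 125 ± 5.16 to 37.8 ± 3.82 CPM, a 3.29-fold fall. PDK4, a kinase that shuts off pyruvate dehydrogenase, fell 4.90-fold and the coactivator PPARGC1A 3.53-fold. CPT1A, which admits long-chain fatty acids to mitochondria, went from 111 ± 1.64 to 81.2 ± 2.37 CPM (log2 -0.45, SE 0.05, adjusted p = 0.000189). Lipoprotein lipase (LPL) fell 2.04-fold and the triglyceride lipase PNPLA2 1.87-fold, while the lysosomal lipase LIPA rose 1.5-fold and the acyl-CoA synthetase ACSL4 1.63-fold.

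In contrast, most enzymes of fatty acid oxidation and ketogenesis rose: 19 of 31 members were higher and 5 lower (20 and 5 adjusted over the list alone, 22 and 5 without PA + DMSO replicate 3), with a median of 0.32. ACADM, which starts the oxidation of medium-chain fatty acids, rose 1.68-fold. The 5 that fell were PDK4, PPARGC1A, CPT1A, CPT1B and ACAA1 (CPT1B and ACAA1 named after their values were seen). This list was higher by camera with an adjusted p of 0.023 (adjusted p = 0.693 with an estimated correlation). It did not pass the threshold by fry (adjusted p = 0.121). Lipoprotein assembly and secretion also rose, with 12 of 21 members higher and 2 lower (12 and 3 adjusted over the list alone, 12 and 3 without PA + DMSO replicate 3), a median of 0.35 and an adjusted p of 0.017 by camera (adjusted p = 0.693 with an estimated correlation). The cholesterol exporter ABCA1 rose 1.51-fold, while APOA4 fell 1.68-fold. The number lower was 1 without PA + DMSO replicate 1 or any single PA + 3-IAA library, and with scaling by library total, no filter or the replicate number as a block.

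Other lipid lists showed no shift by camera. Fatty acid synthesis and desaturation had 6 members higher and 4 lower of 20 (adjusted p = 0.545), with ACACA at 1.61-fold and ACLY at 1.53-fold higher and INSIG1, which restrains sterol-regulated transcription, lower. Lipid droplets and lipolysis had 3 higher and 4 lower of 16 (adjusted p = 0.743), and the 4 lower became 2 without PA + 3-IAA replicate 1 or replicate 3. Fatty acid uptake and activation had 4 higher and 4 lower of 15 (adjusted p = 0.695), and the number higher was 7 without PA + DMSO replicate 3 and 2 without PA + DMSO replicate 1 or 2 or PA + 3-IAA replicate 3. Cholesterol synthesis and uptake had 10 lower and 2 higher of 23 (adjusted p = 0.204). MVD, NSDHL and SC5D, 3 enzymes of the sterol pathway, fell 1.89-fold, 1.95-fold and 1.83-fold. That list's number higher was 11 without PA + DMSO replicate 3, against 1 without any other single library, 6 with scaling by library total and 1 with no filter. In each of these 4 lists the counts adjusted over the list alone were the same.

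Of 7 sirtuins, SIRT3 rose (log2 1.44, SE 0.22, adjusted p = 0.000596), on 31 to 53 counts per library in PA + DMSO and 99 to 145 in PA + 3-IAA. SIRT1 fell 1.84-fold and SIRT7 1.56-fold. SIRT2 was called higher at 0.15 (log2), and 4 sirtuins were higher when adjusted over the list alone or without PA + DMSO replicate 3, against 1 without any other single library. The number was also 4 with scaling by library total, and 1 by DESeq2, with no filter or with the replicate number as a block. The list fixed for targets of SIRT3, which also holds the non-mitochondrial CAT, ACSS2 and FOXO3 (the last 2 named after their values were seen), had 12 of 24 members higher and 3 lower (the same adjusted over the list alone, 14 and 3 without PA + DMSO replicate 3), with an adjusted p of 0.0962 by camera. By fry, without comparison with other genes, that list was higher (adjusted p = 0.0126). The peroxidase PRDX3 rose 1.54-fold and the peroxisomal catalase CAT 1.39-fold, while the mitochondrial protease LONP1 fell 1.89-fold. Nuclear-encoded subunits of the respiratory chain rose, with 26 of 49 higher and 2 lower (the same adjusted over the list alone, 32 and 2 without PA + DMSO replicate 3) and a median of 0.17. NDUFS1 and NDUFA10, subunits of complex I, rose 1.5-fold and 1.58-fold, and cytochrome c (CYCS) fell 1.52-fold. This list had an adjusted p of 0.000145 by camera (adjusted p = 0.693 with an estimated correlation). Of 13 mitochondrially encoded genes 3 were lower and none higher, with a median of -0.09 and an adjusted p of 0.339. The number lower was 0 without PA + 3-IAA replicate 1 or replicate 3 and 1 without PA + DMSO replicate 2 or with scaling by library total.

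Markers of differentiated hepatocytes were higher with 3-IAA: 21 of 27 rose and 3 fell (the same adjusted over the list alone, 22 and 3 without PA + DMSO replicate 3), with a median of 0.48 and an adjusted p of 6.41e-05 by camera (adjusted p = 0.693 with an estimated correlation). The liver transcription factor HNF4A rose 2.09-fold, from 29.4 ± 2.85 to 61.6 ± 1.59 CPM. The transcription factors FOXA2 and CEBPA were among those that fell (named after their values were seen). Acute phase proteins, plasma proteins that the liver makes in inflammation, rose in 18 of 21 cases with none lower (the same adjusted over the list alone and without PA + DMSO replicate 3), with a median of 0.74. Complement factor B (CFB) rose 1.48-fold, fibrinogen gamma (FGG) 1.46-fold and C4BPA 1.4-fold. The list's adjusted p was 2.29e-05 by camera (adjusted p = 0.693 with an estimated correlation).

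Interferon-stimulated genes rose in 26 of 28 cases with none lower (27 higher and 1 lower adjusted over the list alone), and had a median of 1.09. Without PA + DMSO replicate 3 the list had 27 higher and 2 lower, with a further member past the filter, and 1 was lower without any single PA + 3-IAA library or with no filter. HERC6 rose 1.46-fold, CMPK2 1.65-fold and XAF1 2.47-fold. Near-identical members of this list, such as the OAS1 genes, share reads, and their separate counts are uncertain. Camera gave an adjusted p of 4.5e-08 (adjusted p = 0.693 with an estimated correlation). The list of inflammatory cytokines and NF-kB targets did not move as a whole, with 12 lower and 5 higher of 30 (12 and 6 adjusted over the list alone) and an adjusted p of 0.545, where the median was 0.02 and the mean -0.10. Its neutrophil-attracting chemokines CXCL8 and CXCL2 fell 4.43-fold and 2.86-fold, CXCL8 from 10840 ± 2121 to 2448 ± 160 CPM, and the cytokine CSF2 fell 8.42-fold. The number higher was 14 without PA + DMSO replicate 3 and 11 by limma voom over the 6 libraries.

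Genes that handle foreign compounds and oxidants were covered by 3 lists, 2 of which passed camera. CYP1A1, the classic target of the aryl hydrocarbon receptor, went from 30.3 ± 4.47 to 38.9 ± 2.97 CPM (1.29-fold, log2 0.36, SE 0.11, adjusted p = 0.0193), and AHR, the receptor itself, from 39.5 ± 5.39 to 51.0 ± 3.55 CPM (1.29-fold, log2 0.37, SE 0.10, adjusted p = 0.0117). CYP1A1 was no longer called without PA + 3-IAA replicate 2 (log2 0.30), nor AHR without PA + 3-IAA replicate 3 (log2 0.31). The aryl hydrocarbon receptor list had 7 of 15 members higher and 1 lower (the same adjusted over the list alone, 8 and 2 without PA + DMSO replicate 3), with an adjusted p of 0.288 by camera. By fry, which makes no comparison with other genes, that list was higher (adjusted p = 0.00465). The member that fell, STC2, is also an ATF4 target and changed by -2.98 (log2), and NQO1 and UGT1A6 rose 1.64-fold and 1.71-fold. Targets of the pregnane X receptor and related xenobiotic genes had 9 of 17 higher and 2 lower (10 and 2 adjusted over the list alone and without PA + DMSO replicate 3), with a median of 0.59 and an adjusted p of 0.0327 by camera (adjusted p = 0.693 with an estimated correlation). The sulfotransferases SULT1A1 and SULT2A1 rose 1.86-fold and 2.62-fold and the monooxygenase FMO5 2.59-fold. This list did not pass the threshold with scaling by library total or with the strict filter on low counts. NRF2 targets and antioxidant enzymes had 19 of 27 higher and 4 lower (20 and 4 adjusted over the list alone, 20 and 5 without PA + DMSO replicate 3), a median of 0.36 and an adjusted p of 0.00321 by camera (adjusted p = 0.693 with an estimated correlation). Superoxide dismutase 1 (SOD1) and ferritin light chain (FTL) rose 1.62-fold and 1.61-fold. The members that fell were OSGIN1, SLC7A11, GPX4 and SRXN1 (named after their values were seen).

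In the list of tryptophan and kynurenine metabolism 7 of 16 members were higher and 2 lower (the same adjusted over the list alone, 9 and 2 without PA + DMSO replicate 3), with an adjusted p of 0.141 by camera. The list was higher by fry, without comparison with other genes (adjusted p = 0.0329). IDO2, which opens the indole ring of tryptophan, rose 2.19-fold and monoamine oxidase B (MAOB) 2.28-fold. The number lower was 1 without PA + 3-IAA replicate 1 or with scaling by library total.

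Immediate early genes, which respond within minutes to growth and stress signals, had 17 of 27 members lower and 5 higher (the same adjusted over the list alone, 18 and 6 without PA + DMSO replicate 3), with a median of -0.43 and an adjusted p of 0.00477 by camera (adjusted p = 0.693 with an estimated correlation). KLF6 fell 1.64-fold and the phosphatase DUSP6 1.78-fold, whereas FOS, FOSB, FOSL2, JUNB and EGR3 rose (named after their values were seen). Cytosolic ribosomal proteins had 22 of 34 lower and none higher (the same adjusted over the list alone, 30 and 0 without PA + DMSO replicate 3), with small changes: RPLP2 fell 1.31-fold and RPS12 and RPS28 1.32-fold each. The number lower was 12 without PA + DMSO replicate 2, 11 without PA + 3-IAA replicate 1 and 12 without PA + 3-IAA replicate 3. With scaling by library total it was 14, and the median of -0.18 was -0.11. That list's adjusted p was 6.41e-05 by camera (adjusted p = 0.693 with an estimated correlation), and ribosomal protein genes have many processed copies that can share reads. In the list of apoptosis and p53 targets, 11 of 27 members were lower and 7 higher (the same adjusted over the list alone, 12 and 8 without PA + DMSO replicate 3), with an adjusted p of 0.339. By fry, without comparison with other genes, this list was lower (adjusted p = 0.012). The pro-apoptotic genes PMAIP1 and BBC3 fell 3.45-fold and 3.08-fold and GADD45A 4.44-fold.

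**Figure D4:**
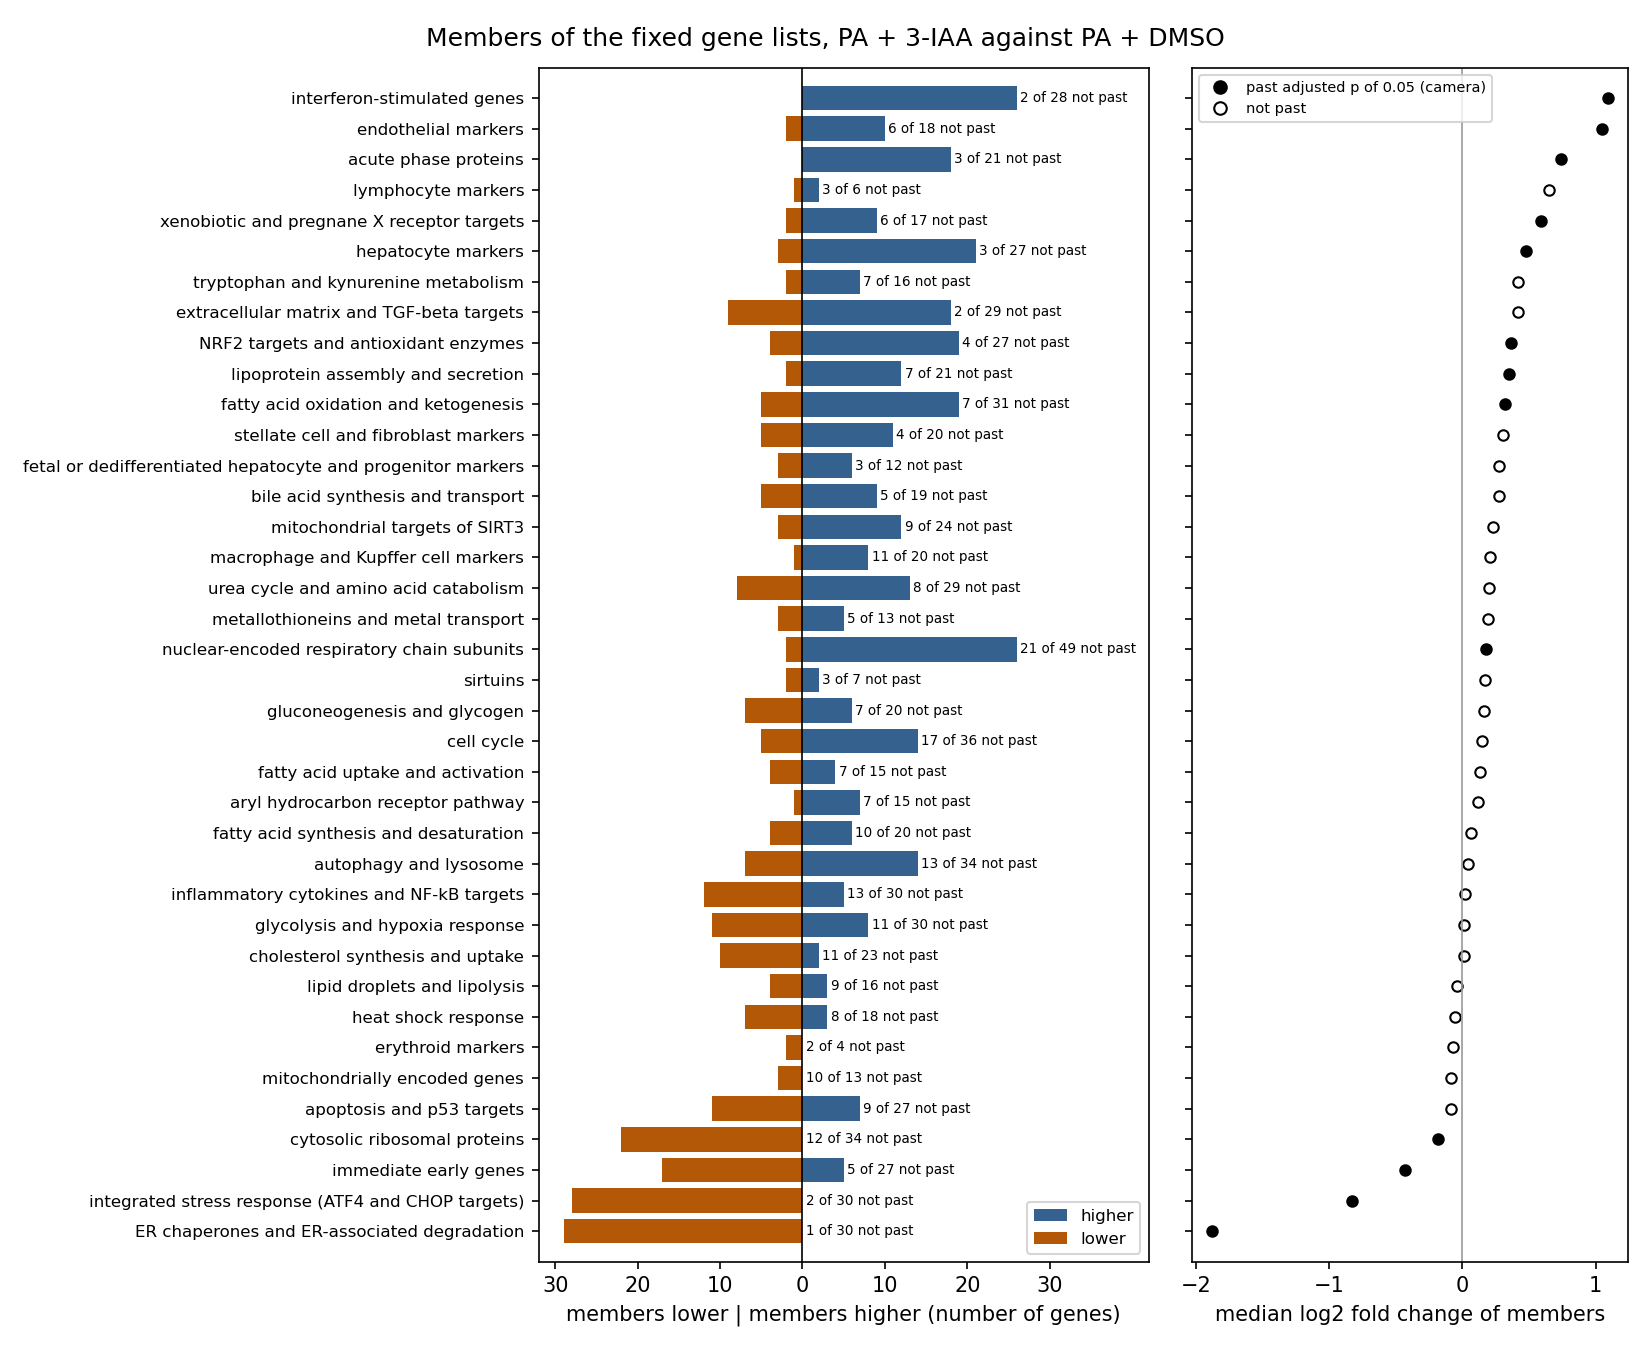
For each fixed list, the number of members lower (left of 0) and higher (right of 0) with 3-IAA, and the median log2 fold change of its tested members (right panel; filled points passed camera with a preset correlation). ER chaperones lie lowest, at -1.88, and interferon-stimulated genes highest, at 1.09.

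Markers of other liver cells were also measured. Endothelial markers had 10 of 18 members higher and 2 lower, with a median of 1.05. The numbers were 12 and 2 adjusted over the list alone, and 14 and 2 without PA + DMSO replicate 3. The list had an adjusted p of 0.00486 by camera (adjusted p = 0.693 with an estimated correlation). It did not pass the threshold by fry (adjusted p = 0.0534). LYVE1 went from 1.47 ± 0.37 to 5.91 ± 0.56 CPM and VWF from 5.38 ± 2.35 to 18.3 ± 1.84 CPM, whereas ESAM went from 18.3 ± 1.25 to 11.8 ± 0.28 CPM and CLDN5, the other that fell, changed by -0.93 (log2; named after its value was seen). The number higher was 6 without PA + DMSO replicate 2 or PA + 3-IAA replicate 1, and the number lower was 1 without PA + DMSO replicate 2 or any single PA + 3-IAA library, and with the strict filter. The lists of macrophage and Kupffer cell markers (median 0.21, adjusted p = 0.158), stellate cell and fibroblast markers (median 0.30, adjusted p = 0.524), lymphocyte markers (median 0.65 over 6 genes, adjusted p = 0.524) and fetal or progenitor markers (median 0.28, adjusted p = 0.524) showed no shift by camera. Only 4 erythroid markers passed the filter, too few for the list test, and their median was -0.07. It was 0.00 with scaling by library total.

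The remaining fixed lists did not pass the threshold in camera with the settings chosen first: cell cycle (median 0.15, adjusted p = 0.0962), extracellular matrix and TGF-beta targets (0.42, adjusted p = 0.158), autophagy and lysosome (0.04, adjusted p = 0.545), gluconeogenesis and glycogen (0.16, adjusted p = 0.629), glycolysis and hypoxia (0.01, adjusted p = 0.601, with a mean of -0.13), bile acid synthesis and transport (0.27, adjusted p = 0.315), urea cycle and amino acid catabolism (0.20, adjusted p = 0.282), heat shock (-0.06, adjusted p = 0.468) and metallothioneins and metal transport (0.19, adjusted p = 0.629, with a mean of -0.05). The heat shock median was 0.02 with scaling by library total. The cell cycle list passed with no filter on low counts (adjusted p = 0.693 with an estimated correlation and the filter). The matrix list passed the threshold without PA + DMSO replicate 3, but not with an estimated correlation (adjusted p = 0.652 with an estimated correlation, also without that library).

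By the annotation deposited with the counts, 95 terms of 2290 were enriched among the higher genes and 37 among the lower ones (one-sided Fisher's exact test, Benjamini-Hochberg adjusted). The strongest among the higher genes was the proteasome complex, of which 44 of 53 members rose and 1 fell, where 14.6 rises would be expected (adjusted p = 1.29e-13). All 15 members of the proteasome accessory complex rose, by a median of 0.73 (log2). Among the lower genes, transport from ER to Golgi led with 54 of 87 members lower and 9 higher (24.3 lower expected, adjusted p = 6.7e-08), followed by protein processing in the ER with 126 of 297 lower (75.9 expected, adjusted p = 1.06e-07). In that wider term 70 members were higher and the median was -0.10. The oligosaccharyltransferase complex, which attaches N-linked sugars in the ER, had 11 of 13 members lower, and loading of COPII vesicles, which leave the ER, 12 of 14, with 1 member higher in each. The number of terms among lower genes was 24 without PA + DMSO replicate 1 or replicate 2. It was 18 with scaling by library total, 20 with the strict filter and 127 with no filter.

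The 8 largest falls by fitted fold, among genes that met the rule for named genes, included 3 ER genes (HSPA5, PDIA4 and DERL3). The rule's minimum, a mean CPM of at least 5 over the 6 libraries, can be met through PA + DMSO alone. In PA + 3-IAA replicates 1 to 3 AMIGO3 had 8, 6 and 0 counts and OSCAR 12, 11 and 12. SPDYC had 9, 14 and 10 there and RAB39B 18, 12 and 17, so the sizes of these 4 folds rest on few counts. AMIGO3 went from 84.0 ± 23.5 to 0.21 ± 0.18 CPM, OSCAR from 38.5 ± 12.6 to 0.53 ± 0.03 CPM, SPDYC from 20.1 ± 6.48 to 0.50 ± 0.13 CPM, CYP2J30 from 26.4 ± 7.76 to 1.45 ± 0.18 CPM and RAB39B from 11.4 ± 4.09 to 0.70 ± 0.13 CPM. In the reference gene table (ARS-UCD2.0), AMIGO3 overlaps GMPPB (log2 -2.07) and SPDYC overlaps SYVN1 (log2 -2.32), and the use of strand in counting was not given, so reads of each pair cannot be fully separated. CYP2J30 belongs to a family of similar genes, which makes its count uncertain. The 8 largest rises were TNFSF10 (2.58 ± 3.02 to 23.5 ± 2.70 CPM, 8.84-fold), TUBB3 (7.55-fold), TCF19 (5.99-fold), MX2 (5.78-fold), ID1 (5.35-fold), TMEM106A (5.22-fold), ETNPPL (5.16-fold) and SLC25A48 (4.75-fold). Leaving out any single library other than PA + DMSO replicate 3 ended the calls of MX2 (log2 2.10 to 2.59) and ID1 (1.94 to 2.47). The call of TMEM106A ended without PA + DMSO replicate 2 (2.27) or PA + 3-IAA replicate 1 (2.33), and that of SLC25A48 without PA + DMSO replicate 2 (1.98) or any single PA + 3-IAA library (2.24 to 2.26). With no filter on low counts MX2, ID1 and SLC25A48 were not called, nor was ID1 with the replicate number as a block (2.66). In each of these rises PA + DMSO replicate 3 was the highest library of its group, with TNFSF10 at 6.07 CPM against 0.79 and 0.88 in the other 2. Without that library the log2 fold changes were larger: 4.82 for TNFSF10 (from 3.15), 4.32 for TUBB3 (from 2.92), 3.98 for TCF19 (from 2.58), 4.01 for MX2 (from 2.53), 4.20 for ID1 (from 2.42), 3.24 for TMEM106A (from 2.39) and 3.31 for SLC25A48 (from 2.25).

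The authors' deposited table of their own comparison, read for 13257 genes, marks 1478 genes as higher and 1536 as lower, and its marks match an adjusted p under 0.05 with a fold of at least 1.5 for every one of those genes. Across the 12521 genes also tested here, its log2 fold changes correlated with those above at a Pearson r of 0.99997 (across genes, which are not independent replicates). Of its 6515 shared genes with an adjusted p under 0.05, 6443 were called in the same direction here and 0 in the opposite one. In the authors' deposited table SIRT3 has a log2 fold change of 1.44 and HSPA5 of -4.34.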

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

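The estimated correlation without PA + DMSO replicate 3, and the counts of list members under each setting, were chosen after seeing the data. Genes higher and lower with 3-IAA stayed within 1.5 times of 3963 and 4015 under each alternative run, from 2984 to 4918 higher and from 3285 to 4726 lower when single libraries were left out. Scaling by library total gave 4820 higher and 3315 lower, so that higher genes outnumbered lower ones. By at least 2-fold, 459 genes were higher and 554 lower with the strict filter, which tested 13086 genes, and from 516 to 1205 were higher with 1 library left out (1205 without PA + DMSO replicate 3). Terms among lower genes numbered 18 with scaling by library total, 127 with no filter, 20 with the strict filter and from 24 to 37 with 1 library left out; the cause was not tested. With an estimated correlation 0 lists were higher and 0 lower, and also 0 and 0 without PA + DMSO replicate 3. fry, which compares no list with other genes, had 19 lists past the threshold. Fatty acid oxidation and endothelial markers passed camera with the preset correlation but not fry. Lists that passed fry but not camera were the aryl hydrocarbon receptor pathway, targets of SIRT3, tryptophan metabolism and the urea cycle. The others were macrophage markers, apoptosis, cholesterol synthesis and heat shock. Among the values of named genes 1625 kept their direction and side of the threshold, 37 lost the call and 2 gained it. Genes that a filter removed have no value in that setting. The strict filter removed AMIGO3, OSCAR, SPDYC, DERL3 and RAB39B among the largest falls. Among the largest rises it removed TNFSF10, TUBB3, TCF19 and ID1, and it also removed FGF21, LCK, SLC51A and EPOR. Among member counts of lists, 881 stayed within 1.5 times and 107 did not. No fold change of a named gene changed sign in the settings run. Medians of 3 lists, none of them called, changed sign with scaling by library total: lipid droplets from -0.04 to 0.03, heat shock from -0.06 to 0.02 and erythroid markers, too few to test, from -0.07 to 0.001. With the replicate number as a block 3721 genes were higher and 3766 lower. Deviations of same-numbered libraries from their group means correlated at 0.05, 0.045 and 0.015 across genes, which are not independent replicates, against -0.065 to 0.016 for other pairs. DESeq2 gives no camera test, so lists have no value under it.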

Other observations

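In this part, the tests of PA + DMSO replicate 3, of the endothelial markers and of AMIGO3 and SPDYC were chosen only after the result was seen. Beyond the groups described above, further annotation terms were enriched. Among the higher genes were 83 of 152 members of the complement and coagulation cascades (16 lower, adjusted p = 6.24e-11), 90 of 190 of the lysosome (34 lower, adjusted p = 1.87e-06) and 72 of 150 of the peroxisome (24 lower, adjusted p = 2.12e-06). Signaling terms enriched among the lower genes went both ways: Wnt signaling had 106 of 284 members lower and 73 higher (adjusted p = 0.00223, median log2 fold change -0.04), FoxO signaling 95 of 257 lower and 63 higher (adjusted p = 0.00572, median -0.07) and ErbB signaling 57 of 136 lower and 26 higher (adjusted p = 0.00514, median -0.11). Terms overlap, so these counts share genes.

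PA + DMSO replicate 3 lay between the groups; a swap of labels with a PA + 3-IAA library needs a partner out of place, and the PA + 3-IAA libraries spanned 0.9% of the first principal component. Material from PA + 3-IAA samples mixed into this library may account for part of the pattern. Over genes changed at least 4-fold its median share of the way was 0.40 for risen and 0.43 for fallen genes, a difference of 0.03. Only 1 gene lay over 1.5-fold outside the range of the other 5 libraries. A weaker response would also place the library between the groups, so these values do not tell the 2 apart. Against a single mixing share as the whole cause, 4 of 48 combinations of list and direction lay apart from random lists of called genes and beyond the spread of the other libraries, such as cholesterol synthesis, with medians of 1.05 for risen and 0.12 for fallen members. In the fatty acid lists 11 fallen members with a mean CPM of at least 5 had a median share of 0.05. That lay below the 2.5% quantile of random lists of called genes, 0.26. PLIN2 (-0.29), MGLL (-0.34), CPT1A (-0.08), SLC27A5 (-0.01), PDK4 (0.04) and CD36 (0.05) had not moved towards PA + 3-IAA or hardly so. SLC27A1 (0.31), ACAA1 (0.43), LPL (0.54), PNPLA2 (0.56) and ACSL3 (1.20) had. A share is uncertain where the groups differ little, as for ACSL3 (log2 -0.15 without PA + DMSO replicate 3) and MGLL (-0.20). Likewise without that library, PLIN2 (-2.33), PDK4 (-2.30) and CD36 (-1.73) fell most. LPL (-1.18) and PNPLA2 (-1.05), which had moved, also fell clearly. The upper quartile of these 11 members, 0.49, passed the 0.40 of the pool, so as a set they do not decide it. The 14 fallen members with no such minimum had a median of 0.21 and an upper quartile of 0.45, and 31 risen members a median of 0.41. A mixture together with other differences of this sample stays open, as does a weaker response of its cells, which was not tested, since no PA-free sample was among these libraries.

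Of 18 endothelial markers tested, 10 were higher and 2 lower (adjusted p = 0.693 with an estimated correlation), and 6 were higher without PA + DMSO replicate 2 or PA + 3-IAA replicate 1. A lower share of hepatocytes is argued against by the hepatocyte markers, whose median log2 fold change was 0.475. More endothelial cells alone would not lower members of the list, and 11.1% of the tested markers fell, 2 of 18. The number was 1 without PA + DMSO replicate 2, without any single PA + 3-IAA library or with the strict filter. Among all genes tested 4015 of 15576 fell, a larger share, so these falls do not decide the question. For the members that rose, the folds differed beyond their standard errors (p = 8.41e-09 by Cochran's Q against a chi-square distribution, n = 10 genes measured in the same 6 libraries). This could come from other cells expressing some of them, so more endothelial cells stays open.

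AMIGO3 and SPDYC each overlap a gene that fell less. If a fixed share of GMPPB reads had been counted as AMIGO3, both would fall alike, but AMIGO3 fell by 6.53 (SE 0.53) further on the log2 scale. Likewise SPDYC fell by 3 (SE 0.41) further than SYVN1. Reads from another transcript at these loci stay open, and no biological explanation was tested.

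The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 7978 genes and the highest other 0, 1547 genes at 2-fold against 0, and 132 terms against 0. Every other split holds both treatments in each group, so the treatment difference enters the spread within groups. Counts of 0 there say little about chance, and without called genes no term can be enriched. For gene lists the real split gave 13 and the highest other also 13, so 2 of the 10 splits gave as many lists. Each other count was reached by 1 split, the real one. The other splits divide the treatments unevenly, so part of the treatment difference stays between their groups and camera can call lists from it. Their numbers of lists therefore do not measure chance either.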
